A study of Macaca mulatta with 22 samples.

How the data were processed

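The samples are 22 single rhesus macaque oocytes and embryos, 7 oocyte and 15 embryo libraries, each taken as 1 replicate of its stage: 5 stages have 2 libraries and 4 have 3. Per the labels' protocols, oocytes were collected post mortem from superovulated donors, and embryos came from intracytoplasmic sperm injection and in vitro culture. Per the same protocols, RNA of each oocyte or embryo was amplified with the SMARTer Ultra Low Input kit, which primes on poly(A), and libraries were made with a TruSeq DNA kit. 

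The authors deposited 1 table of RPKM values with 35468 entries and 22 columns, each matched to 1 sample by its title. Of the entries 28595 have Ensembl identifiers (ENSMMUG) and 6873 have identifiers starting with IMMRNTR. Per the submitters' processing notes the genome build is Mmul_8.0.1, while the file itself names no build, so chromosome positions are printed as deposited. The aligner, counting program and annotation release are not given.

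Symbols came first from the name table given with the task, which holds 15556 of the Ensembl identifiers, and otherwise from the file (6032). No symbol was found for 7007. Entries starting with IMMRNTR carry a name from the file that could not be checked, so their identifier is printed with the name. A symbol can have several entries, and reads of near-identical copies can be split between them.

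Depth was estimated from the low values of features spanning less than 200 bp, taken as single exons, where values are whole multiples of 1 read. Of 516 such values, 463 (89.7%) were within 0.05 of a whole number of reads, and the libraries came to 5.62 to 21.52 M reads.

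The main test was limma (version 3.58.1 in R 4.3.3) on log2(RPKM + 1), with 1 mean per stage over all 22 libraries, 13 residual degrees of freedom, and empirical Bayes moderation with a trend and robust settings. Entries with at least 1 RPKM in at least 2 libraries were tested, 14312 in all (12060 ENSMMUG and 2252 IMMRNTR). The log2 changes are on the log2(RPKM + 1) scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg within each comparison, and a call is a 2-sided adjusted p under 0.05. The comparisons were the 8 neighbouring pairs of stages, GV to MII, the mean of PN, 2C and 4C against the mean of 8C, Mo and Bl, and a limma F test over the 9 stages.

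The 22 gene lists were written from general knowledge before the table was opened. Each was tested with limma's camera at a preset correlation of 0.01 if at least 3 members were tested, with Benjamini-Hochberg adjustment over all 220 tests. Members were also adjusted over the list alone. KHDC1 and KHDC1L share 1 entry, so the genome activation list has 23 tested. Genes are named by a rule fixed with the lists: those with a symbol, called, with libraries of the 2 stages that do not overlap and at least 10 RPKM on average in the higher stage, the largest log2 changes in each direction (8 for GV to MII, 4C to 8C, 8C to Mo and Mo to Bl, 4 for other pairs). The rule adds, for lists with at least 3 called members or a camera call, up to 4 called members with the smallest adjusted p, and a panel of 24 genes. In the first part only ENSMMUG entries were used, because the names of the others could not be checked; that departs from the rule as fixed. The second part takes more genes than the text can hold and was cut, after the values were seen, by order alone: the 2 members with the smallest adjusted p for lists called by camera and 1 for other lists, and from early to late embryos 1 for called lists, with 1 for the other lists in the closing section. The members left out have larger p-values and lose their calls more often, so each comparison also gives how many genes of the whole rule lose the call. A gene was counted as first detected at a stage if it was below 0.5 RPKM in every library of all earlier stages and at least 2 RPKM in every library of the stage.

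The alternatives were a pseudocount of 0.1, no filter, at least 5 RPKM in 2 libraries, median-of-ratios scaling (reference of 5405 entries above 0 in all libraries), a fit of only the stages compared, the replicate number as a factor, each library left out in turn, an estimated correlation in camera and other detection thresholds. Fits without Mo library 2 for stages other than its own, and stage means without 1 library where they move by over 1.5 times (given for stages of 3 libraries, for the panel and for the higher stage of other genes, since with 2 the SD gives both values), were added after the data were seen.

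Scripts were tested on simulated changes with each gene's mean and a residual SD equal in all stages. Of changes of 3 log2 units, 42% were recovered from 4C to 8C, 66% from 8C to Mo, 52% from Mo to Bl and 54% from GV to MII. An uncalled gene can have changed. Of calls, 2.9%, 4.3%, 8.9% and 6.2% were false, but real rates can differ. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sample was left out.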

Results

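The deposited RPKM table describes 22 single rhesus macaque oocytes and embryos at 9 stages: germinal vesicle (GV, n = 2), metaphase I (MI, n = 2) and metaphase II (MII, n = 3) oocytes, then pronuclear (PN, n = 3), 2-cell (2C, n = 2), 4-cell (4C, n = 3), 8-cell (8C, n = 2), morula (Mo, n = 3) and blastocyst (Bl, n = 2) embryos. Per the labels' protocols oocytes were taken post mortem and embryos made by injection and culture, so MII and PN also differ in source. No label names an animal or donor, so gene p-values measure only the spread between single oocytes and embryos, pooled over stages. Camera's p-values compare genes.

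Genes of a fixed panel differed in the stages at which their values were high (mean ± SD RPKM of the stage). The panel of 24 genes was fixed before the data were examined, and 22 of them were matched (TPRX1 and EIF1AX were not). BTG4, an adaptor of the deadenylase that removes maternal mRNA, was 3863 ± 478 at MII, 1988 ± 65.4 at 4C, 409 ± 9.43 at 8C and 9.80 ± 6.50 at Bl. The zona pellucida gene ZP3 was 3133 ± 619 at MI, 899 ± 625 at MII, 142 ± 161 at 2C and 18.3 ± 0.202 at 8C, and the oocyte linker histone H1FOO was 634 ± 214 at MII and 0.446 ± 0.531 at Mo. The secreted factor GDF9 (IMMRNTR2410) was 312 ± 119 at MI, 207 ± 65.8 at 4C and 1.28 ± 0.799 at Mo, and NLRP5, a member of the subcortical maternal complex, was 267 ± 34.996 at GV, 45.6 ± 42.1 at 8C and 0.284 ± 0.439 at Mo. DPPA3 (IMMRNTR2887), which guards maternal DNA methylation, was 10139 ± 457 at MII, 13638 ± 1305 at 2C, 10493 ± 1273 at 4C, 4017 ± 823 at 8C, 7061 ± 4268 at Mo and 1615 ± 128 at Bl. The homeobox gene DUXA was 2.43 ± 0.550 at 4C, 3722 ± 778 at 8C, 2019.6 ± 1505 at Mo and 35.99 ± 22.2 at Bl, with LEUTX (IMMRNTR1244, 7.27 ± 1.76 at 4C and 1167 ± 511 at 8C), ZSCAN4 (2.61 ± 1.24 at 4C and 545 ± 259.6 at 8C), ARGFX (0.892 ± 0.783 at 4C and 1767 ± 1118 at Mo) and KLF17 (0.025 ± 0.044 at 4C and 41.98 ± 14.8 at 8C) in the same interval. The pluripotency genes NANOG (11.6 ± 8.22 at 8C and 117 ± 23.3 at Mo) and DNMT3L (0.260 ± 0.368 at 8C and 157 ± 104 at Bl) came later, and the blastocysts held the epithelial keratin KRT18 (26.6 ± 36.9 at Mo and 1043 ± 231 at Bl), the trophectoderm regulator GATA3 (0.320 ± 0.518 at Mo and 18.5 ± 3.76 at Bl) and the methyltransferase DNMT3B (33.6 ± 15.8 at PN, 2.31 ± 2.04 at Mo and 113 ± 11.4 at Bl). POU5F1 was 1.74 ± 1.26 at 4C, 19.5 ± 21.3 at Mo and 12.6 ± 4.07 at Bl, GATA6 was 6.83 ± 2.25 at Bl, CDX2 was 7.23 ± 0.732 at GV and 1.497 ± 0.936 at Bl, and XIST (IMMRNTR4737) was 0.012 ± 0.017 at 8C, 12.8 ± 18.7 at Mo and 2.64 ± 2.77 at Bl. SOX2 (0.036 ± 0.051 at Bl) and MOS (0.115 ± 0.083 at GV and 2.57 ± 3.29 at PN) were low throughout, and SOX2 was not tested. Means of 3 libraries that move by over 1.5 times when 1 is left out are, without MII library 3 ZP3 538, without PN library 2 MOS 0.682, without 4C library 3 ARGFX 0.440 and KLF17 0, without Mo library 1 DUXA 1244, GATA3 0.021 and DNMT3B 1.40, without Mo library 2 KRT18 5.37, GATA3 0.480, POU5F1 7.29 and XIST 2.03, without Mo library 3 H1FOO 0.144 and NLRP5 0.032. In an F test over the 9 stages, limma called 9778 of 14312 tested genes (68.3%).

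**Figure D1:**
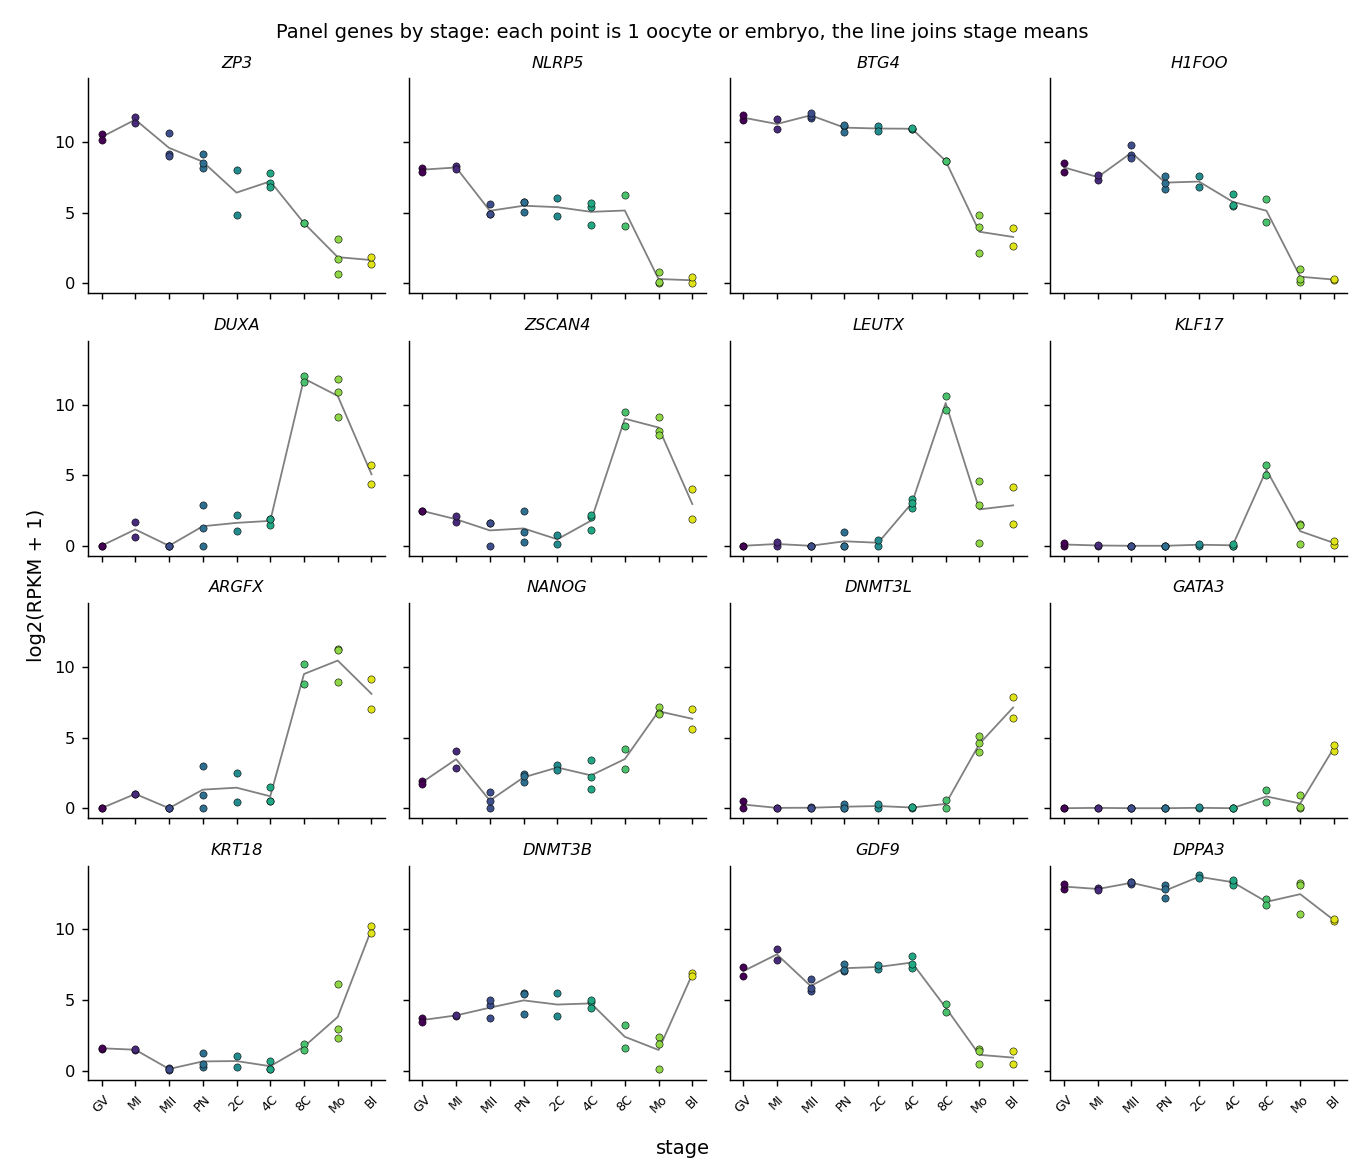
Expression of 16 panel genes over the 9 stages as log2(RPKM + 1). Points are single oocytes or embryos and lines join the stage means.

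Libraries of the same stage resembled each other most at GV and MI, and least at 8C and in the pairs with Mo library 2. Correlations of log2(RPKM + 1) within a stage were 0.972 for GV and for MI, 0.945 to 0.96 for MII, 0.894 to 0.956 for PN, 0.903 for 2C, 0.92 to 0.939 for 4C, 0.836 for 8C, 0.74 to 0.952 for Mo and 0.916 for Bl. The first 3 principal components held 45.6%, 11.8% and 8.4% of the variance. Mo library 2 stands apart: at 20.165 M reads it holds 4277 genes at 1 RPKM or more, and the other libraries hold 6763 to 10017. It stays in every test.

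In the main test the most genes were called from 4C to 8C, from 8C to Mo and from Mo to Bl. The order depends on the fit: with only the stages compared the totals are 3299 from MI to MII, 3099 from 4C to 8C, 1589 from MII to PN, 1571 from 8C to Mo and 9 from Mo to Bl, and without Bl library 1 the last is 936 in the main test. At adjusted p < 0.05, limma called 1989 genes higher and 1453 lower at 8C than at 4C, 771 higher and 2865 lower at Mo than at 8C, and 1721 higher and 303 lower at Bl than at Mo. During maturation the counts were 30 higher and 54 lower from GV to MI and 213 higher and 1000 lower from MI to MII. After it they were 681 and 416 from MII to PN, 18 and 49 from PN to 2C and 54 and 28 from 2C to 4C. RPKM is relative to each library's reads. The median log2 change of all tested genes is -0.15 from MI to MII (-0.01 under scaling) and -0.19 from GV to MII (-0.04). It is 0 from 4C to 8C (0.08), -0.38 from 8C to Mo (-0.27) and 0.23 from Mo to Bl (0.08).

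**Figure D2:**
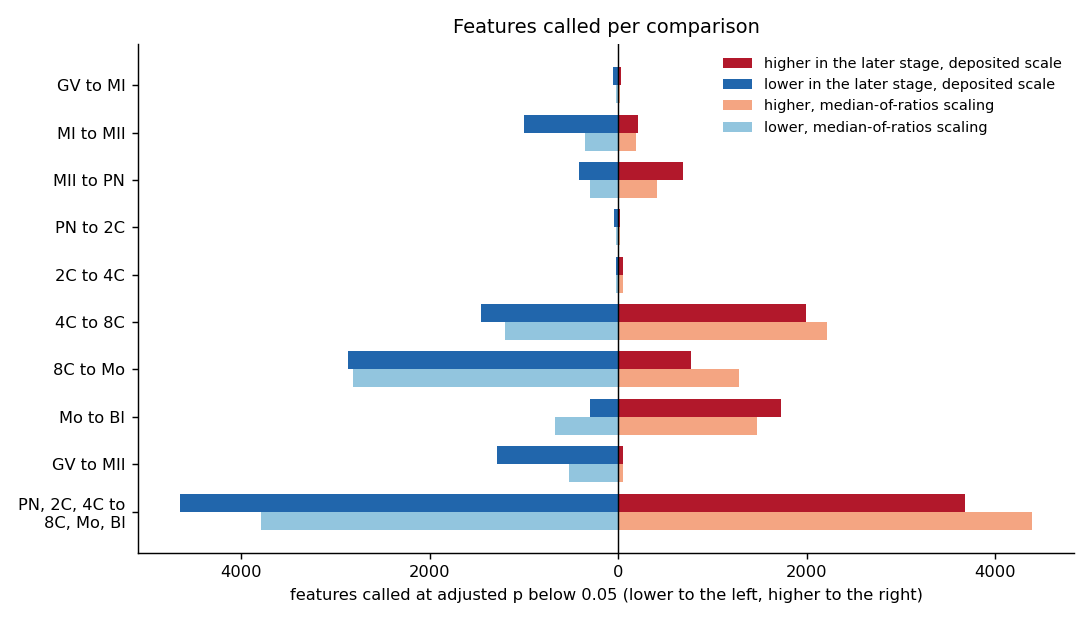
Genes called higher and lower by limma (adjusted p < 0.05) in each comparison, as deposited and under median-of-ratios scaling.

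Most genes called between GV and MII oocytes had lower values at MII (mean ± SD RPKM, n = 2 and 3). The largest decreases between libraries that do not overlap were in LAMTOR4 (233 ± 0.703 to 9.97 ± 9.996), LGALS4 (206 ± 1.66 to 6.17 ± 4.87), CCDC167 (1798 ± 79.3 to 63.9 ± 29.7) and MED31 (109 ± 20.8 to 4.15 ± 4.12). Next came the isoprenoid enzyme FDPS (58.5 ± 2.58 to 2.11 ± 2.68), the defensin DEFB116 (73.8 ± 27.4 to 2.35 ± 1.28), the complex I subunit NDUFA9 (29.6 ± 4.37 to 0.461 ± 0.465) and the calcium-binding S100A11 (88.4 ± 12.1 to 4.45 ± 4.30). LGALS4 (ENSMMUG00000028766, chromosome 19 from 45144615 to 45155169) fell by 5.05 log2 units (limma adjusted p = 6.27e-04). The largest increases were in IFI27 (3.28 ± 3.41 to 44.6 ± 22.3), RAB13 (2.42 ± 0.651 to 33.6 ± 12.95), SLC19A2 (1.21 ± 0.163 to 20.3 ± 12.4) and LIG4 (2.69 ± 3.03 to 20.47 ± 3.20). HMGN5 (4.98 ± 5.44 to 28.8 ± 11.3), KCTD13 (5.93 ± 4.71 to 25.4 ± 4.51), TSTD2 (11.6 ± 2.67 to 52.3 ± 12.2) and DIRAS2 (77.1 ± 30.7 to 292 ± 31.4) rose as well. In all, limma called 49 genes higher and 1284 lower, and 54 higher and 529 lower under median-of-ratios scaling. Other settings give 12 and 624 with a pseudocount of 0.1 and 671 and 2473 with a fit of only these stages. Higher and lower counts become 9 and 222 without GV library 1, 7 and 446 without GV library 2, 30 and 940 without MII library 1, 24 and 679 without MII library 2 and 172 and 1835 without Mo library 2. The naming rule takes 49 genes here, and 42 of them lose the limma call without some library. Leaving out 1 library ends calls (limma adjusted p): GV library 2 those of IFI27 (0.0922), SLC19A2 (0.0654), LIG4 (0.0512), HMGN5 (0.507), KCTD13 (0.457), TSTD2 (0.248), DIRAS2 (0.185), LAMTOR4 (0.14), CCDC167 (0.0532) and MED31 (0.174), GV library 1 those of RAB13 (0.0922), SLC19A2 (0.0754), LIG4 (0.453), HMGN5 (0.0579), KCTD13 (0.0748), TSTD2 (0.161), DIRAS2 (0.0555), LAMTOR4 (0.167), CCDC167 (0.0767), MED31 (0.162), DEFB116 (0.106) and S100A11 (0.0721), MII library 1 those of LIG4 (0.0713), HMGN5 (0.0531), KCTD13 (0.0824) and TSTD2 (0.0811), MII library 2 those of LIG4 (0.0937), HMGN5 (0.152), KCTD13 (0.138), TSTD2 (0.132), LAMTOR4 (0.127) and MED31 (0.124), and MII library 3 those of LIG4 (0.0886), HMGN5 (0.0938), KCTD13 (0.0792), TSTD2 (0.0584) and MED31 (0.0625). Calls also end with a pseudocount of 0.1 (IFI27, LIG4, HMGN5, KCTD13, TSTD2, DIRAS2, LAMTOR4, MED31 and DEFB116), no filter on low values (LIG4, HMGN5, KCTD13, TSTD2, LAMTOR4 and MED31) and median-of-ratios scaling (LIG4, HMGN5, TSTD2, LAMTOR4 and MED31). Mean RPKM without MII library 3 is 13.4 for SLC19A2. The libraries were primed on poly(A), so tail length can move these values too.

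Members of several gene lists were called from GV to MII (camera's higher and lower are relative to other genes). Of 17 subcortical maternal complex genes 0 rose and 5 fell, 0 and 5 over the list alone. PADI6 (435 ± 114 to 63.97 ± 17.7) fell. Of 16 oocyte and germline factor genes 0 rose and 3 fell, 0 and 4 over the list alone. TBPL2 (88.9 ± 2.50 to 16.6 ± 4.30) fell. Of 41 meiotic maturation and spindle genes 1 rose and 2 fell, 2 and 2 over the list alone, and the list was higher (median log2 change 0.49, limma's camera adjusted p = 0.00239, adjusted p = 0.348 with estimated correlation). AURKA (687 ± 43.3 to 1826 ± 59.8) rose and CDK1 (412 ± 85.5 to 86.9 ± 50.6) fell. Of 38 maternal RNA storage and decay genes 1 rose and 6 fell, 1 and 7 over the list alone. ZAR1 (159 ± 11.1 to 19.4 ± 6.55) fell. Of 71 cytosolic ribosomal protein genes 1 rose and 1 fell, 0 and 0 over the list alone, and the list was higher (median log2 change 0.29, limma's camera adjusted p = 0.00109, adjusted p = 0.939 with estimated correlation). RPS18 (IMMRNTR2481, 22.5 ± 0.795 to 58.2 ± 8.51) rose and RPL19 (ENSMMUG00000004235, 18.4 ± 5.63 to 6.14 ± 3.50) fell. Of 62 ribosome biogenesis genes 1 rose and 9 fell, 1 and 12 over the list alone. UTP18 (24.01 ± 8.74 to 2.33 ± 1.09) fell. Of 38 translation factor genes 0 rose and 4 fell, 0 and 5 over the list alone. EIF2B2 (16.99 ± 0.231 to 1.01 ± 0.820) fell. Of 56 spliceosome genes 0 rose and 6 fell, 0 and 6 over the list alone. SNRPD2 (434 ± 48.1 to 39.96 ± 11.97) fell. Of 58 DNA methylation and chromatin genes 1 rose and 1 fell, 0 and 0 over the list alone. The list was higher (median log2 change 0.04, all genes -0.19, camera adjusted p = 0.0125 and 0.513 with estimated correlation). DNMT1 (369 ± 58.2 to 1057 ± 142) rose and EZH2 (12.1 ± 2.31 to 2.65 ± 0.848) fell. Of 56 oxidative phosphorylation genes 0 rose and 16 fell, 0 and 24 over the list alone, and the list was lower (median log2 change -1.45, limma's camera adjusted p = 5.48e-05, adjusted p = 0.786 with estimated correlation). ATP5MC1 (343 ± 37.3 to 23.9 ± 10.4) fell. Single libraries hold up calls (limma adjusted p without each): GV library 1 those of TBPL2 (0.0645), CDK1 (0.128), AURKA (0.268), ZAR1 (0.0692), RPS18 (0.215), RPL19 (0.364), UTP18 (0.0747), EIF2B2 (0.0982), EZH2 (0.239) and DNMT1 (0.138), GV library 2 those of CDK1 (0.177), AURKA (0.178), RPS18 (0.21), RPL19 (0.101), UTP18 (0.14), EIF2B2 (0.0733), EZH2 (0.109) and DNMT1 (0.216), MII library 2 those of CDK1 (0.123), AURKA (0.103), RPS18 (0.129), EZH2 (0.11) and DNMT1 (0.0956), MII library 1 those of AURKA (0.102), RPS18 (0.0626), RPL19 (0.125) and DNMT1 (0.0718), and MII library 3 those of AURKA (0.0868), RPS18 (0.0792), RPL19 (0.13) and EZH2 (0.0592). Some calls end with a pseudocount of 0.1 (TBPL2, AURKA, RPS18, RPL19, EZH2 and DNMT1), median-of-ratios scaling (CDK1, AURKA, RPL19, UTP18, EZH2 and DNMT1) and no filter on low values (AURKA and RPL19).

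In the main test few genes were called between GV and MI (n = 2 and 2). PCBP1 rose (15.4 ± 0.518 to 250.2 ± 51.1), as did SYCP3 (0.024 ± 0.034 to 32.4 ± 0.226). RPS3A (8.85 ± 2.32 to 113 ± 25.7) and RPS29 on chromosome 4 (1.99 ± 0.504 to 39.8 ± 1.82) rose. RPS29's more abundant entry ENSMMUG00000029367 fell without a call (153 to 42.1). The secreted hormone gene STC1 fell (18.9 ± 9.87 at GV and listed at 0 in every MI library), with the monooxygenase gene FMO2 (63.4 ± 9.67 to 13.96 ± 1.09) and RPL19 entry ENSMMUG00000000294 (10.47 ± 1.31 to 0.512 ± 0.268), while entry ENSMMUG00000004235 of RPL19 rose (18.4 to 148), a call that ends without GV library 2, MI library 1 or MI library 2 (limma adjusted p = 0.102, 0.059 and 0.102). Below, RPL19 is the entry that fell. RPS18 (IMMRNTR2481, 22.5 ± 0.795 to 0.215 ± 0.072) fell by 4.27 log2 units (limma adjusted p = 1.98e-05). Among 71 cytosolic ribosomal protein genes 2 rose and 1 fell, 2 and 1 over the list alone. Of 9 zona pellucida and secreted factor genes 0 rose and 0 fell, 0 and 0 over the list alone, and the list was higher (median log2 change 0.83, limma's camera adjusted p = 7.70e-04, adjusted p = 0.331 with estimated correlation). Among 41 meiotic maturation and spindle genes 0 rose and 0 fell, 0 and 0 over the list alone, and the list was higher (median log2 change 0.20, limma's camera adjusted p = 0.00714, adjusted p = 0.482 with estimated correlation). Without adjustment limma at 0.05 has 2 zona pellucida genes higher, and 2 meiotic genes higher and 0 lower. limma called 30 genes higher and 54 lower, and 14 higher and 26 lower under median-of-ratios scaling. Of these 84, 34 belong to 52 that set GV and MII apart from MI, PN, 2C and 4C in every library, among them PCBP1, RPS3A, RPS29, STC1 and RPS18. Higher and lower counts are 29 and 30 with a pseudocount of 0.1, 52 and 121 with no filter, 27 and 26 with the filter of 5 RPKM and 221 and 335 with a fit of only these stages. With libraries left out they are 6 and 21 without GV library 1, 10 and 30 without GV library 2, 7 and 26 without MI library 1 and 7 and 22 without MI library 2. Of 9 genes the naming rule takes here, 5 lose the limma call without some library. The loss of 1 library ends calls (limma adjusted p): GV library 1 those of SYCP3 (0.0911), RPS29 (0.0583), RPL19 (0.0823) and FMO2 (0.19), GV library 2 those of SYCP3 (0.0852), RPL19 (0.102) and FMO2 (0.334), MI library 1 those of SYCP3 (0.0919), RPL19 (0.0675) and FMO2 (0.357), and MI library 2 those of SYCP3 (0.102), RPL19 (0.149) and FMO2 (0.244). There are calls that end with median-of-ratios scaling (SYCP3 and RPL19) and a pseudocount of 0.1 (FMO2).

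From MI to MII most called genes fell (n = 2 and 3). The largest decreases were in LGALS4 (186 ± 66.8 to 6.17 ± 4.87), CDK5 (241 ± 19.6 to 9.13 ± 7.79), SYCP3 (32.4 ± 0.226 to 0.264 ± 0.457) and FDPS (62.1 ± 18.4 to 2.11 ± 2.68). The largest increases were in IFI27 (0.680 ± 0.113 to 44.6 ± 22.3), RAB13 (0.381 ± 0.252 to 33.6 ± 12.95), RPL32 (1.85 ± 0.685 to 36.03 ± 3.59) and SLC19A2 (1.13 ± 0.346 to 20.3 ± 12.4). RPL32 here is ENSMMUG00000015130; the more abundant entry ENSMMUG00000001340 was not called (402 to 356). The maternal methyltransferase DNMT1 rose (169.7 ± 18.2 to 1057 ± 142, limma adjusted p = 8.66e-04). limma called 213 genes higher and 1000 lower (17.6% higher), and 192 higher and 359 lower under median-of-ratios scaling (34.8% higher). Of the 1213, 45 are among the 52 that set GV and MII apart, with RPL32, RPS18 and RPL19. The split becomes 112 and 567 with a pseudocount of 0.1 and 899 and 2400 with a fit of only these stages. Leaving libraries out gives 53 and 181 without MI library 1, 51 and 225 without MI library 2, 112 and 457 without MII library 2 and 402 and 1584 without Mo library 2. When some library is left out, 29 of the 40 genes the naming rule takes here lose the limma call. Among 17 subcortical maternal complex genes 1 rose and 5 fell, 1 and 7 over the list alone. PADI6 (343 ± 24.2 to 63.97 ± 17.7) fell. Among 38 maternal RNA storage and decay genes 1 rose and 4 fell, 3 and 7 over the list alone. PATL2 (67.9 ± 4.19 to 12.3 ± 3.46) fell. In the cytosolic ribosomal protein list 6 of 71 genes rose and 3 fell, 7 and 3 over the list alone, and the list was higher (median log2 change 0.65, limma's camera adjusted p = 6.76e-06, adjusted p = 0.813 with estimated correlation). RPS18 (IMMRNTR2481, 0.215 ± 0.072 to 58.2 ± 8.51) rose and RPL19 (ENSMMUG00000004235, 148 ± 16.6 to 6.14 ± 3.50) fell. Among 62 ribosome biogenesis genes 2 rose and 4 fell, 3 and 7 over the list alone. NOP2 (8.32 ± 2.71 to 0.204 ± 0.216) fell. Among 38 translation factor genes 0 rose and 5 fell, 1 and 6 over the list alone. EIF3D (23.8 ± 12.8 to 1.60 ± 0.680) fell. Among 56 spliceosome genes 2 rose and 4 fell, 2 and 4 over the list alone. SNRPA1 (51.5 ± 11.2 to 7.597 ± 3.14) fell. Among 58 DNA methylation and chromatin genes 1 rose and 0 fell, 1 and 0 over the list alone. The list was higher (median log2 change 0.17, all genes -0.15, camera adjusted p = 0.0123 and 0.513 with estimated correlation). Among 56 oxidative phosphorylation genes 0 rose and 8 fell, 1 and 16 over the list alone, and the list was lower (median log2 change -1.17, limma's camera adjusted p = 0.00725, adjusted p = 0.939 with estimated correlation). NDUFA9 (34.2 ± 12.5 to 0.461 ± 0.465) and ATP5F1A (439 ± 48.8 to 66.7 ± 4.07) fell. Of 27 stress, p53 and apoptosis genes 1 rose and 2 fell, 1 and 2 over the list alone. DNAJB1 (90.97 ± 17.5 to 18.4 ± 7.18) fell. Calls end (limma adjusted p) when 1 library is left out: MI library 2 those of RPL32 (0.074), SLC19A2 (0.0899), CDK5 (0.0598), PATL2 (0.073), NOP2 (0.0985), EIF3D (0.0523), SNRPA1 (0.0746) and DNAJB1 (0.0966), MI library 1 those of SLC19A2 (0.0632), CDK5 (0.0542), PATL2 (0.0958), EIF3D (0.186), ATP5F1A (0.0518) and DNAJB1 (0.0518), and MII library 2 that of EIF3D (0.0502). Other settings end calls, namely median-of-ratios scaling (EIF3D and DNAJB1). Mean RPKM without MII library 3 is 13.4 for SLC19A2.

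PN embryos differed from MII oocytes in genes of many classes (n = 3 and 3). The largest increases were in SYCP3 (0.264 ± 0.457 to 65.4 ± 22.9), MAP1LC3C (2.92 ± 3.14 to 82.9 ± 15.7), RPS29 (2.57 ± 0.942 to 67.5 ± 26.5) and ZNF57 (0.198 ± 0.342 to 19.5 ± 13.8), of which RPS29 is the entry on chromosome 4; the other (ENSMMUG00000029367) was not called (169 to 71.4). The smooth muscle actin gene ACTA2 fell (38.8 ± 6.87 to 0.019 ± 0.032, ENSMMUG00000009341, chromosome 9 from 88514985 to 88574330), with VTCN1 (78.8 ± 18.1 to 2.78 ± 2.50) and PDCD5 (3022 ± 2047 to 100.2 ± 18.7) and RPL15 entry ENSMMUG00000021980 (358 ± 76.7 to 20.8 ± 24.5). ACTA2 fell by 5.28 and VTCN1 fell by 4.58 log2 units (limma adjusted p = 6.88e-08 and 1.06e-05). In the meiotic maturation and spindle list 1 of 41 genes rose and 2 fell, 1 and 2 over the list alone. TUBB8 (IMMRNTR5601, 1346 ± 674 to 111 ± 80.7) fell. In the maternal RNA storage and decay list 4 of 38 genes rose and 0 fell, 4 and 0 over the list alone. DDX6 (0.962 ± 0.290 to 11.3 ± 3.78) rose. Of 71 cytosolic ribosomal protein genes 5 rose and 7 fell, 5 and 9 over the list alone, and the list was lower (median log2 change -0.38, limma's camera adjusted p = 0.00639, adjusted p = 0.992 with estimated correlation). RPL19 (ENSMMUG00000004235, 6.14 ± 3.50 to 90.2 ± 39.9) rose and RPS18 (IMMRNTR2481, 58.2 ± 8.51 to 0.543 ± 0.481) fell. In the ribosome biogenesis list 3 of 62 genes rose and 2 fell, 7 and 3 over the list alone. PES1 (0.291 ± 0.125 to 3.22 ± 0.585) rose. In the spliceosome list 3 of 56 genes rose and 5 fell, 4 and 5 over the list alone. PRPF8 (1.10 ± 0.427 to 10.6 ± 4.97) rose. Of 33 epithelial junction and fluid transport genes 2 rose and 1 fell, 2 and 1 over the list alone. ATP1B1 (238 ± 83.7 to 51.1 ± 2.20) fell. In the oxidative phosphorylation list 5 of 56 genes rose and 5 fell, 5 and 8 over the list alone. UQCRB (17.9 ± 4.30 to 1.31 ± 0.377) fell. Among 27 stress, p53 and apoptosis genes 4 rose and 1 fell, 5 and 1 over the list alone. TXNIP (0.593 ± 0.532 to 11.7 ± 6.05) rose. limma called 681 genes higher and 416 lower. All 52 that set GV and MII apart are among them (RPS29 and RPS18 above), and so are all 25 that set PN and 4C apart from the other stages up to 4C (VTCN1 and RPL15). Scaling gives 413 higher and 300 lower. Other settings give 529 and 276 with a pseudocount of 0.1 and 899 and 690 with a fit of only these stages. Higher and lower counts become 352 and 227 without MII library 1, 360 and 336 without MII library 2, 407 and 246 without MII library 3, 629 and 276 without PN library 1, 371 and 299 without PN library 2, 476 and 268 without PN library 3 and 975 and 687 without Mo library 2. The naming rule takes 38 genes here, and 13 of them lose the limma call without some library. Leaving out 1 library ends calls (limma adjusted p): MII library 1 that of ATP1B1 (0.123), MII library 3 that of ATP1B1 (0.111), PN library 1 that of ATP1B1 (0.0742), PN library 2 that of ATP1B1 (0.082), and PN library 3 that of ATP1B1 (0.0865). Calls also end with a pseudocount of 0.1 (ATP1B1) and no filter on low values (ATP1B1). Mean RPKM without PN library 3 is 12.5 for ZNF57.

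Few genes were called over the first 2 cleavages. From PN to 2C (n = 3 and 2) the immune checkpoint gene VTCN1 rose (2.78 ± 2.50 to 78.2 ± 10.9), as did RPL15 (20.8 ± 24.5 to 261 ± 119, entry ENSMMUG00000021980; entry ENSMMUG00000006353 was not called, 265 to 144). TMEM129 (17.1 ± 7.28 to 0.338 ± 0.409) and CCDC59 (22.8 ± 14.4 to 0.716 ± 1.01) fell, and so did TFF3 (154 ± 106 to 9.002 ± 3.39) and MAP1LC3B (48.1 ± 10.7 to 1.53 ± 1.28). VTCN1 changed by 4.59 log2 units (limma adjusted p = 2.42e-04). Among 71 cytosolic ribosomal protein genes 0 rose and 1 fell, 0 and 2 over the list alone, and the list was lower (median log2 change -0.59, limma's camera adjusted p = 9.69e-04, adjusted p = 0.939 with estimated correlation). Without PN library 2 (camera adjusted p = 0.118) or 2C library 1 (camera adjusted p = 0.942) that list is not called. RPL10A (62.1 ± 14.1 to 18.1 ± 2.13) fell. Of 56 oxidative phosphorylation genes 0 rose and 0 fell, 0 and 0 over the list alone, and the list was lower (median log2 change -0.63, limma's camera adjusted p = 0.0147, adjusted p = 0.975 with estimated correlation). Without PN library 2 (camera adjusted p = 0.324) or 2C library 1 (camera adjusted p = 0.175) that list is not called. Without adjustment limma at 0.05 has 0 oxidative phosphorylation genes higher and 4 lower. limma called 18 genes higher and 49 lower (26.9% higher), and 22 higher and 29 lower under scaling (43.1% higher). Of these 67, 17 are among the 25 that set PN and 4C apart, with VTCN1, RPL15 and TMEM129. Higher and lower counts are 11 and 26 with a pseudocount of 0.1, 28 and 56 with no filter and 2 and 14 with a fit of only these stages. With libraries left out they are 7 and 42 without PN library 3, 36 and 55 without 2C library 1, 14 and 17 without 2C library 2 and 28 and 91 without Mo library 2. Of 7 genes the naming rule takes here, 5 lose the limma call without some library. Single libraries hold up calls (limma adjusted p without each): PN library 3 those of RPL15 (0.0527) and RPL10A (0.0755), 2C library 2 those of RPL15 (0.179), MAP1LC3B (0.127), TFF3 (0.0904) and RPL10A (0.173), 2C library 1 those of CCDC59 (0.0813) and RPL10A (0.161), PN library 1 that of RPL10A (0.0784), and PN library 2 that of RPL10A (0.141). Some calls end with a fit of only these stages (RPL15 and RPL10A), a pseudocount of 0.1 (TFF3 and RPL10A) and median-of-ratios scaling (RPL10A). Mean RPKM without PN library 2 is 14.7 for CCDC59 and 93.4 for TFF3.

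From 2C to 4C (n = 2 and 3) the 2C libraries are those of the comparison above, so opposite changes can come from these 2 libraries alone. VTCN1 fell (78.2 ± 10.9 to 0.927 ± 0.931), the same entry of RPL15 fell (261 ± 119 to 11.7 ± 3.21), TMEM129 rose (0.338 ± 0.409 to 13.7 ± 2.33) and CCDC59 rose (0.716 ± 1.01 to 25.4 ± 15.97). RFPL4B (0.892 ± 1.26 to 26.7 ± 14.6) and HACD3 (0.292 ± 0.218 to 11.2 ± 2.55) rose, and WFDC2 (252 ± 194 to 30.01 ± 7.25) and ACBD3 (47.97 ± 14.5 to 7.68 ± 2.60) fell. VTCN1 changed by -5.46 log2 units (limma adjusted p = 6.67e-05). In the cytosolic ribosomal protein list 2 of 71 genes rose and 0 fell, 2 and 0 over the list alone, and the list was higher (median log2 change 0.64, limma's camera adjusted p = 5.80e-09, adjusted p = 0.738 with estimated correlation). Without 2C library 1 (camera adjusted p = 0.0751) that list is not called. RPL10A (18.1 ± 2.13 to 72.4 ± 9.31) and RPL3 (34.5 ± 12.3 to 240.1 ± 115) rose. limma called 54 genes higher and 28 lower, and 21 of these 82 are among the 25 that set PN and 4C apart, with VTCN1, RPL15, TMEM129 and ACBD3. The split becomes 34 and 18 with a pseudocount of 0.1 and 23 and 14 with a fit of only these stages. Leaving libraries out gives 41 and 57 without 2C library 1, 18 and 25 without 2C library 2, 38 and 12 without 4C library 1, 57 and 14 without 4C library 2 and 77 and 47 without Mo library 2. When some library is left out, 8 of the 10 genes the naming rule takes here lose the limma call. The loss of 1 library ends calls (limma adjusted p): 2C library 1 those of CCDC59 (0.0599), RFPL4B (0.152), HACD3 (0.0544), ACBD3 (0.12), RPL10A (0.0886) and RPL3 (0.187), 4C library 1 those of RFPL4B (0.0746), WFDC2 (0.0709), ACBD3 (0.0811), RPL10A (0.0751) and RPL3 (0.136), 2C library 2 those of RPL15 (0.119), WFDC2 (0.385), ACBD3 (0.0588), RPL10A (0.0811) and RPL3 (0.0918), 4C library 2 that of WFDC2 (0.108), and 4C library 3 those of WFDC2 (0.0751) and RPL3 (0.0692). There are calls that end with a pseudocount of 0.1 (RFPL4B and WFDC2), no filter on low values (WFDC2 and RPL3), median-of-ratios scaling (WFDC2) and a fit of only these stages (ACBD3 and RPL10A). Mean RPKM without 4C library 2 is 16.3 for CCDC59.

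At the 8-cell stage homeobox and associated genes had high values (n = 3 at 4C and 2 at 8C). DUXA rose (2.43 ± 0.550 to 3722 ± 778, ENSMMUG00000007788, chromosome 19 from 63011895 to 63017246), with KHDC1L (2.63 ± 1.26 to 2748 ± 753), ARGFX (0.892 ± 0.783 to 825 ± 553) and CCNA1 (0.129 ± 0.117 to 283 ± 71.9). The PRAME family genes PRAMEF10 (0.084 ± 0.076 to 239 ± 80.7) and PRAMEF6 (0.818 ± 1.17 to 244 ± 36.2) and NANOGNB (0.212 ± 0.240 to 214 ± 33.4) and TIMM8A (0.556 ± 0.888 to 249 ± 140.4) rose as well. DUXA changed by 10.08 and KHDC1L by 9.59 log2 units (limma adjusted p = 1.29e-08 and 6.99e-09). The largest decreases were in TFF3 (60.4 ± 20.4 to 0.106 ± 0.149), CEP44 (73.8 ± 16.2 to 1.25 ± 0.131), CAPZA1 (231 ± 185 to 8.59 ± 10.3) and PRG3 (24.4 ± 10.8 to 0.028 ± 0.040), then in FGF14 (75.4 ± 20.7 to 2.64 ± 1.65), ZNF224 (26.2 ± 6.59 to 0.268 ± 0.038), USP2 (524 ± 377 to 20.7 ± 13.999) and ZNF420 (263 ± 129 to 11.3 ± 0.857). TFF3 fell by 5.75 log2 units (limma adjusted p = 1.05e-06). limma called 1989 genes higher and 1453 lower, and 2218 higher and 1201 lower under median-of-ratios scaling, where 1172 of the 1453 lower calls (80.7%) stay. Other settings give 1298 and 1385 with the filter of 5 RPKM. Higher and lower counts become 1311 and 839 without 8C library 1. The naming rule takes 84 genes here, and 20 of them lose the limma call without some library. Calls end (limma adjusted p) when 1 library is left out: 4C library 1 that of CAPZA1 (0.0505), and 8C library 1 that of CAPZA1 (0.184). Mean RPKM without 4C library 1 is 140.2 for CAPZA1. PRAME family entries are close copies, so their levels are uncertain.

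Members of genome activation, lineage and metabolism lists were called from 4C to 8C. Of 23 genome activation genes 20 rose and 0 fell, 20 and 0 over the list alone, and the list was higher (median log2 change 5.06, limma's camera adjusted p = 1.14e-15 and 0.00311 with estimated correlation). KLF17 (0.025 ± 0.044 to 41.98 ± 14.8) rose. Of 20 pluripotency and epiblast genes 8 rose and 1 fell, 9 and 1 over the list alone, and the list was higher (median log2 change 1.05, limma's camera adjusted p = 0.0175, adjusted p = 0.348 with estimated correlation). Without 8C library 1 (camera adjusted p = 0.0919) that list is not called. L1TD1 (0.441 ± 0.383 to 132 ± 4.20) and LEFTY2 (0.058 ± 0.101 to 1.44 ± 0.183) rose. Of 13 primitive endoderm genes 2 rose and 1 fell, 2 and 1 over the list alone. FRZB (56.7 ± 8.35 to 7.92 ± 4.36) fell. Of 29 trophectoderm and trophoblast genes 4 rose and 3 fell, 5 and 3 over the list alone. CGA (0.207 ± 0.267 to 53.8 ± 28.4) rose. Among 33 epithelial junction and fluid transport genes 4 rose and 1 fell, 4 and 1 over the list alone. AQP11 (0.116 ± 0.200 to 2.91 ± 0.691) rose. In the DNA methylation and chromatin list 10 of 58 genes rose and 3 fell, 10 and 3 over the list alone. KDM5B (0.916 ± 0.345 to 90.3 ± 5.66) rose. Among 56 oxidative phosphorylation genes 10 rose and 1 fell, 10 and 1 over the list alone. COX7A2 (IMMRNTR4994, 0.498 ± 0.190 to 12.8 ± 5.61) rose. Of 17 glycolysis genes 6 rose and 1 fell, 8 and 1 over the list alone, and the list was higher (median log2 change 1.77, limma's camera adjusted p = 0.0167, adjusted p = 0.348 with estimated correlation). HK2 (0.232 ± 0.188 to 6.07 ± 0.663) rose and PDK1 (29.6 ± 12.7 to 5.01 ± 3.69) fell. In the stress, p53 and apoptosis list 9 of 27 genes rose and 1 fell, 9 and 1 over the list alone. SESN2 (0.014 ± 0.024 to 25.1 ± 11.6) rose. Leaving out 1 library ends calls (limma adjusted p): 8C library 2 that of PDK1 (0.059).

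Members of maternal lists were called at the same step. In the subcortical maternal complex list 1 of 17 genes rose and 5 fell, 1 and 6 over the list alone, and the list was lower (median log2 change -0.64, limma's camera adjusted p = 0.0436, adjusted p = 0.713 with estimated correlation). Without 4C library 1 (camera adjusted p = 0.056) or 8C library 1 (camera adjusted p = 0.543) that list is not called. Scaling ends its call (camera adjusted p = 0.0869). TENT5C (165 ± 80.8 to 12.8 ± 9.68) and OOEP (560.2 ± 309 to 65.2 ± 43.7) fell. Among 9 zona pellucida and secreted factor genes 0 rose and 4 fell, 0 and 8 over the list alone, and the list was lower (median log2 change -1.60, limma's camera adjusted p = 0.00136, adjusted p = 0.348 with estimated correlation). GDF9 (IMMRNTR2410, 207 ± 65.8 to 21.6 ± 6.23) and BMP15 (172 ± 73.3 to 37.8 ± 7.61) fell. Among 16 oocyte and germline factor genes 1 rose and 7 fell, 1 and 7 over the list alone. MAEL (319 ± 91.6 to 45.4 ± 19.9) fell. Of 41 meiotic maturation and spindle genes 0 rose and 8 fell, 0 and 8 over the list alone, and the list was lower (median log2 change -0.69, limma's camera adjusted p = 0.0245, adjusted p = 0.551 with estimated correlation). Without 8C library 1 (camera adjusted p = 0.0941) that list is not called. AURKA (927 ± 81.8 to 129 ± 34.6) and CCNB3 (76.7 ± 22.2 to 9.85 ± 5.48) fell. Of 38 maternal RNA storage and decay genes 3 rose and 6 fell, 3 and 7 over the list alone. YTHDF2 (3.30 ± 1.91 to 87.3 ± 44.7) rose. Single libraries hold up calls (limma adjusted p without each): 8C library 1 that of OOEP (0.064), and 8C library 2 that of BMP15 (0.0616).

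Growth and RNA processing lists had called members from 4C to 8C too. Of 71 cytosolic ribosomal protein genes 10 rose and 0 fell, 10 and 0 over the list alone. FAU (38.6 ± 10.2 to 2612 ± 995) rose. Of 62 ribosome biogenesis genes 25 rose and 0 fell, 28 and 1 over the list alone, and the list was higher (median log2 change 1.14, limma's camera adjusted p = 5.13e-06, adjusted p = 0.222 with estimated correlation). POLR1C (0.124 ± 0.082 to 58.1 ± 35.1) and NOL11 (1.45 ± 0.979 to 51.3 ± 23.5) rose. In the translation factor list 9 of 38 genes rose and 3 fell, 10 and 4 over the list alone. EIF3I (5.03 ± 2.24 to 192 ± 119) rose. Of 56 spliceosome genes 17 rose and 3 fell, 20 and 3 over the list alone, and the list was higher (median log2 change 0.55, limma's camera adjusted p = 0.0022, adjusted p = 0.222 with estimated correlation). SNRPB2 (IMMRNTR4951, 0.069 ± 0.119 to 12.6 ± 2.74) and SRSF3 (5.09 ± 1.57 to 309.5 ± 139.6) rose.

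Counting genes under 0.5 RPKM in every earlier library and at 2 RPKM or more in every library of a stage, 229 were first detected at 8C, against 34 at MI, 1 at MII, 6 at PN, 0 at 2C, 1 at 4C, 6 at Mo and 32 at Bl. 8C has 486 without its library 1 and 571 without its library 2, Mo has 24 without its library 2 and 12 without its library 3, and Bl has 95 without its library 1 and 90 without its library 2.

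More genes were called lower than higher from 8C to Mo (n = 2 and 3). The largest decreases were in NLRP4 (707 ± 253 to 2.63 ± 0.889), RFPL4B (1237 ± 78.9 to 6.94 ± 6.47), CMKLR2 (267 ± 85.98 to 0.270 ± 0.254) and SH3BGRL (131 ± 66.3 to 0.431 ± 0.747) and 4 entries of TRIM49. Those entries were TRIM49 (ENSMMUG00000030952, 292 ± 74.99 to 0.186 ± 0.073), TRIM49 (ENSMMUG00000010216, 283 ± 35.2 to 0.207 ± 0.154), TRIM49 (ENSMMUG00000010218, 279 ± 45.5 to 0.664 ± 0.434) and TRIM49 (ENSMMUG00000023800, 149 ± 0.212 to 0.427 ± 0.298), near-identical copies whose single values are uncertain. NLRP4 (ENSMMUG00000028711, chromosome 19 from 61858139 to 61900533) fell by 7.59 log2 units (limma adjusted p = 2.13e-10). The largest increases were in TMEM45A (1.01 ± 0.614 to 364 ± 198), the cap-binding factor EIF4E (11.2 ± 1.14 to 1917 ± 2060.1), the lactate dehydrogenase LDHB (69.97 ± 78.3 to 2551 ± 1222) and PYROXD1 (0.296 ± 0.349 to 53.7 ± 17.1). GSTO1 (1.77 ± 1.68 to 103 ± 78.3), SPTLC2 (0.088 ± 0.036 to 51.3 ± 49.2), RPL22L1 (33.9 ± 37.9 to 968 ± 668) and DUSP11 (1.25 ± 0.937 to 71.1 ± 36.7) rose too. TMEM45A changed by 7.40 log2 units (limma adjusted p = 1.22e-07). Of the 8-cell genes in the panel, LEUTX and KLF17 fell by 7.54 and 4.35 log2 units (limma adjusted p = 3.07e-06 and 5.36e-08), and DUXA, ZSCAN4 and ARGFX were not called (0.26, 0.596 and 0.481). limma called 771 genes higher and 2865 lower (21.2% higher), and 1275 higher and 2816 lower under scaling (31.2% higher). Higher and lower counts are 128 and 1443 with a fit of only these stages. With libraries left out they are 429 and 2335 without 8C library 2. Of 86 genes the naming rule takes here, 8 lose the limma call without some library. Mean RPKM without Mo library 2 is 728 for EIF4E, 58.001 for GSTO1 and 23.4 for SPTLC2.

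Maternal and genome activation lists had called members from 8C to Mo. Of 17 subcortical maternal complex genes 0 rose and 10 fell, 1 and 10 over the list alone, and the list was lower (median log2 change -3.20, limma's camera adjusted p = 1.14e-04, adjusted p = 0.277 with estimated correlation). NLRP14 (86.2 ± 13.5 to 0.430 ± 0.317) fell. In the zona pellucida and secreted factor list 0 of 9 genes rose and 6 fell, 0 and 6 over the list alone, and the list was lower (median log2 change -2.85, limma's camera adjusted p = 0.0152, adjusted p = 0.52 with estimated correlation). ZP2 (47.1 ± 31.3 to 0.477 ± 0.330) and BMP15 (37.8 ± 7.61 to 1.53 ± 1.14) fell. In the oocyte and germline factor list 2 of 16 genes rose and 8 fell, 2 and 8 over the list alone. DAZL (38.2 ± 0.377 to 0.667 ± 0.647) fell. Among 41 meiotic maturation and spindle genes 4 rose and 8 fell, 4 and 8 over the list alone. TUBB8 (IMMRNTR5601, 49.97 ± 41.5 to 0.823 ± 0.269) fell. Among 38 maternal RNA storage and decay genes 2 rose and 13 fell, 3 and 15 over the list alone. BTG4 (409 ± 9.43 to 15.3 ± 11.96) fell. Among 23 genome activation genes 1 rose and 11 fell, 1 and 12 over the list alone, and the list was lower (median log2 change -1.35, limma's camera adjusted p = 0.00675, adjusted p = 0.277 with estimated correlation). SLC34A2 (45.8 ± 20.8 to 0.024 ± 0.042) and KDM4E (IMMRNTR844, 17.7 ± 5.81 to 0.022 ± 0.038) fell. Of 58 DNA methylation and chromatin genes 4 rose and 20 fell, 5 and 20 over the list alone. DNMT1 (215 ± 81.9 to 4.86 ± 2.75) fell. Of 8 sperm genes 1 rose and 2 fell, 1 and 3 over the list alone. TNP1 (25.3 ± 28.1 at 8C and listed at 0 in every Mo library) fell.

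Translation and metabolism lists had them as well. Among 71 cytosolic ribosomal protein genes 25 rose and 1 fell, 26 and 1 over the list alone, and the list was higher (median log2 change 1.29, limma's camera adjusted p = 1.14e-15, adjusted p = 0.491 with estimated correlation). RPL10A (98.3 ± 1.19 to 538 ± 137) and RPL19 (ENSMMUG00000004235, 187 ± 29.2 to 1395 ± 444) rose. Among 62 ribosome biogenesis genes 8 rose and 4 fell, 8 and 3 over the list alone. The list was higher (median log2 change 0.07, all genes -0.38, camera adjusted p = 0.00394 and 0.513 with estimated correlation). UTP15 (10.2 ± 3.43 to 52.6 ± 11.4) rose and DDX10 (174 ± 27.6 to 31.9 ± 12.6) fell. Of 38 translation factor genes 8 rose and 1 fell, 8 and 0 over the list alone, and the list was higher (median log2 change 0.50, limma's camera adjusted p = 5.48e-05, adjusted p = 0.222 with estimated correlation). EIF3E (46.9 ± 10.4 to 356 ± 137) rose. Among 56 spliceosome genes 5 rose and 5 fell, 4 and 5 over the list alone. SNRPB2 (IMMRNTR4951, 12.6 ± 2.74 to 0.059 ± 0.102) fell. In the oxidative phosphorylation list 8 of 56 genes rose and 4 fell, 8 and 1 over the list alone, and the list was higher (median log2 change 0.57, limma's camera adjusted p = 2.79e-05, adjusted p = 0.785 with estimated correlation). KCTD14 (ENSMMUG00000017471, 2.51 ± 1.41 to 55.3 ± 34.2) and UQCRB (2.15 ± 0.223 to 19.3 ± 8.49) rose. Among 17 glycolysis genes 5 rose and 2 fell, 6 and 2 over the list alone, and the list was higher (median log2 change 1.24, limma's camera adjusted p = 0.00706, adjusted p = 0.296 with estimated correlation). ENO2 (0.215 ± 0.088 to 6.38 ± 1.004) and LDHA (66.1 ± 2.87 to 1167 ± 523) rose. Of 27 stress, p53 and apoptosis genes 2 rose and 6 fell, 2 and 6 over the list alone. DNAJB1 (119.9 ± 19.6 to 12.97 ± 4.75) fell. KCTD14 was matched to its list through an older name and may not belong to it, and another entry of it (ENSMMUG00000001000) fell (30.5 to 0.473). Some calls end with a pseudocount of 0.1 (UTP15) and a fit of only these stages (UTP15 and UQCRB). Mean RPKM without Mo library 3 is 36.2 for KCTD14.

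Lineage and epithelial lists had members going both ways. Among 20 pluripotency and epiblast genes 3 rose and 6 fell, 3 and 6 over the list alone. DNMT3L (0.260 ± 0.368 to 23.8 ± 9.58) rose. Among 13 primitive endoderm genes 2 rose and 1 fell, 1 and 1 over the list alone. HNF4A (0.005 ± 0.007 to 20.9 ± 20.7) rose. Among 29 trophectoderm and trophoblast genes 3 rose and 5 fell, 3 and 6 over the list alone. CGA (53.8 ± 28.4 to 0.636 ± 1.10) fell. In the epithelial junction and fluid transport list 2 of 33 genes rose and 8 fell, 2 and 8 over the list alone. PARD3 (15.8 ± 3.94 to 1.36 ± 1.22) fell. There are calls that end with a fit of only these stages (PARD3). Mean RPKM without Mo library 2 is 8.90 for HNF4A.

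Most genes called between Mo and Bl rose (n = 3 and 2). The largest increases were in the calcium-binding genes S100P (0.437 ± 0.404 to 1200.4 ± 343) and S100A10 (4.004 ± 3.53 to 515 ± 387), the placental gene PLAC8 (1.49 ± 1.97 to 501 ± 62.1) and the fatty acid carrier FABP4 (0.774 ± 0.747 to 402 ± 240.0). MT1E (1.45 ± 1.38 to 756 ± 484), LY6G6C (0.061 ± 0.064 to 292 ± 215), ANXA2 (19.4 ± 26.4 to 1012 ± 356) and IFITM3 (21.5 ± 18.7 to 1123 ± 485) rose too. S100P (ENSMMUG00000021887, chromosome 5 from 2109347 to 2112982) changed by 9.72 log2 units (limma adjusted p = 1.63e-10). MT1E and IFITM3 have close copies in the genome, so their levels are uncertain. The largest decreases were in the 8-cell genes DUXA (2019.6 ± 1505 to 35.99 ± 22.2), ZSCAN4 (356 ± 169.9 to 9.03 ± 8.97), ZIM3 (219.6 ± 25.9 to 7.02 ± 8.38) and CCNA1 (111 ± 31.6 to 3.98 ± 2.25), and then in GIP (158 ± 222 to 1.13 ± 1.44), ETNPPL (84.8 ± 93.2 to 2.64 ± 3.74), YPEL5 (1306 ± 1197 to 47.4 ± 11.8) and TMEM45A (364 ± 198 to 24.03 ± 26.9). DUXA fell by 5.55 log2 units (limma adjusted p = 4.66e-05). limma called 1721 genes higher and 303 lower (85% higher), and 1470 higher and 671 lower under scaling (68.7% higher). The split becomes 9 and 0 with a fit of only these stages. Leaving libraries out gives 842 and 94 without Bl library 1 and 1458 and 447 without Mo library 2. When some library is left out, 28 of the 76 genes the naming rule takes here lose the limma call. Calls end (limma adjusted p) when 1 library is left out: Bl library 1 that of ETNPPL (0.0697). Other settings end calls, namely a fit of only these stages (ANXA2, S100A10, IFITM3, DUXA, ZSCAN4, ZIM3, GIP, CCNA1, ETNPPL, YPEL5 and TMEM45A). Mean RPKM without Mo library 1 is 1244 for DUXA and 29.6 for GIP, and without Mo library 2 is 31.8 for ETNPPL and 616 for YPEL5.

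Trophectoderm and other lineage lists had called members from Mo to Bl, and of these lists camera called only trophectoderm. In the pluripotency and epiblast list 8 of 20 genes rose and 1 fell, 9 and 1 over the list alone. DNMT3B (2.31 ± 2.04 to 113 ± 11.4) rose. In the primitive endoderm list 4 of 13 genes rose and 0 fell, 5 and 1 over the list alone. DAB2 (6.44 ± 6.44 to 55.5 ± 24.98) rose. In the trophectoderm and trophoblast list 17 of 29 genes rose and 0 fell, 19 and 0 over the list alone, and the list was higher (median log2 change 1.27, limma's camera adjusted p = 1.50e-07 and 0.0142 with estimated correlation). Without Bl library 2 (camera adjusted p = 0.0625) that list is not called. VGLL1 (0.034 ± 0.059 to 48.95 ± 19.96) and GATA2 (listed at 0 in every Mo library and 10.3 ± 0.921 at Bl) rose. Of 33 epithelial junction and fluid transport genes 9 rose and 0 fell, 9 and 0 over the list alone. RAB25 (1.09 ± 1.83 to 85.1 ± 40.4) rose. Of 14 cholesterol genes 5 rose and 1 fell, 7 and 1 over the list alone. ACAT2 (0.890 ± 0.657 to 54.96 ± 23.8) rose. Calls also end with a fit of only these stages (DNMT3B, DAB2, VGLL1, GATA2, RAB25 and ACAT2).

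Genome activation and maternal lists also had called members. Among 17 subcortical maternal complex genes 3 rose and 1 fell, 3 and 1 over the list alone. NLRP2 (47.2 ± 8.83 to 380.5 ± 108) rose. Of 16 oocyte and germline factor genes 2 rose and 2 fell, 2 and 2 over the list alone. BOLL (4.82 ± 2.23 to 0.139 ± 0.165) fell. In the meiotic maturation and spindle list 1 of 41 genes rose and 3 fell, 0 and 3 over the list alone, and the list was lower (median log2 change 0.03, limma's camera adjusted p = 0.0324, adjusted p = 0.557 with estimated correlation). Lower is relative: all tested genes have a median of 0.23 (list mean 0.05). Without Mo library 1 (camera adjusted p = 0.0928) or Mo library 3 (camera adjusted p = 0.0955) or Bl library 2 (camera adjusted p = 0.347) that list is not called. AURKC (50.7 ± 31.1 to 8.16 ± 2.62) and CENPF (75.2 ± 25.6 to 18.6 ± 15.6) fell. In the maternal RNA storage and decay list 4 of 38 genes rose and 0 fell, 3 and 0 over the list alone. TOB1 (1.08 ± 0.937 to 15.6 ± 12.9) rose. In the genome activation list 0 of 23 genes rose and 4 fell, 2 and 5 over the list alone, and the list was lower (median log2 change -0.77, limma's camera adjusted p = 1.54e-04, adjusted p = 0.217 with estimated correlation). Among 58 DNA methylation and chromatin genes 11 rose and 2 fell, 12 and 3 over the list alone. TET2 (0.161 ± 0.244 to 32.1 ± 31.03) rose. Single libraries hold up calls (limma adjusted p without each): Bl library 1 those of CENPF (0.251) and TOB1 (0.0912). Some calls end with a fit of only these stages (NLRP2, BOLL, AURKC, CENPF, TOB1 and TET2). Mean RPKM without Mo library 3 is 33.1 for AURKC.

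Metabolism and growth lists had members called in this interval. In the ribosome biogenesis list 2 of 62 genes rose and 4 fell, 2 and 4 over the list alone, and the list was lower (median log2 change 0.01, limma's camera adjusted p = 0.0119, adjusted p = 0.557 with estimated correlation). Lower is relative too (mean -0.05). Without Mo library 3 (camera adjusted p = 0.0684) or Bl library 2 (camera adjusted p = 0.304) that list is not called. DDX49 (0.300 ± 0.332 to 3.92 ± 3.10) rose and RRN3 (14.9 ± 12.4 to 2.48 ± 2.17) fell. Among 38 translation factor genes 6 rose and 1 fell, 7 and 2 over the list alone. EEF1G (17.2 ± 19.9 to 549 ± 166) rose. Of 56 oxidative phosphorylation genes 35 rose and 0 fell, 48 and 0 over the list alone, and the list was higher (median log2 change 2.43, limma's camera adjusted p = 6.73e-15, adjusted p = 0.348 with estimated correlation). NDUFA8 (13.3 ± 2.97 to 187 ± 70.3) and NDUFS8 (0.417 ± 0.472 to 113 ± 145) rose. In the glycolysis list 5 of 17 genes rose and 2 fell, 6 and 3 over the list alone. ENO2 (6.38 ± 1.004 to 0.020 ± 0.028) fell. Among 27 stress, p53 and apoptosis genes 6 rose and 2 fell, 6 and 2 over the list alone. GADD45B (0.582 ± 0.512 to 4.81 ± 3.41) rose. The loss of 1 library ends calls (limma adjusted p): Bl library 1 those of DDX49 (0.157), RRN3 (0.309) and GADD45B (0.129), and Mo library 2 that of RRN3 (0.0816). There are calls that end with a pseudocount of 0.1 (DDX49 and GADD45B) and a fit of only these stages (DDX49, RRN3, EEF1G, NDUFA8, NDUFS8, ENO2 and GADD45B). Mean RPKM without Mo library 2 is 7.82 for RRN3.

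The 8 embryos of 1 to 4 cells (early) and the 7 from 8C on (late) differ in most tested genes (mean ± SD RPKM from early to late, n = 8 and 7). limma called 3674 genes higher in late embryos and 4646 lower (44.2% higher), and 4387 higher and 3793 lower under scaling (53.6% higher). Other settings give 2427 and 3671 with the filter of 5 RPKM. The stages are averaged with equal weight in the test, and the SDs hold the differences between stages too. The naming rule takes 87 genes here, and 2 of them lose the limma call without some library. In the subcortical maternal complex list 1 of 17 genes rose and 15 fell, 1 and 15 over the list alone, and the list was lower (median log2 change -3.72, limma's camera adjusted p = 6.76e-06, adjusted p = 0.222 with estimated correlation). NLRP4 (871 ± 321 to 204 ± 359) fell. Of 9 zona pellucida and secreted factor genes 0 rose and 8 fell, 0 and 8 over the list alone, and the list was lower (median log2 change -4.65, limma's camera adjusted p = 3.53e-05, adjusted p = 0.222 with estimated correlation). GDF9 (IMMRNTR2410, 176 ± 47.2 to 6.99 ± 10.3) fell. Among 16 oocyte and germline factor genes 1 rose and 12 fell, 1 and 12 over the list alone, and the list was lower (median log2 change -2.33, limma's camera adjusted p = 0.00229, adjusted p = 0.217 with estimated correlation). DAZL (158 ± 72.3 to 11.6 ± 18.2) fell. Of 41 meiotic maturation and spindle genes 7 rose and 21 fell, 7 and 21 over the list alone, and the list was lower (median log2 change -0.69, limma's camera adjusted p = 0.0281, adjusted p = 0.551 with estimated correlation). Without 8C library 1 (camera adjusted p = 0.0521) or Bl library 2 (camera adjusted p = 0.0691) that list is not called. Scaling ends its call (camera adjusted p = 0.104). AURKA (1067 ± 189 to 55.6 ± 53.2) fell. Of 38 maternal RNA storage and decay genes 4 rose and 19 fell, 4 and 19 over the list alone, and the list was lower (median log2 change -0.81, limma's camera adjusted p = 0.028, adjusted p = 0.657 with estimated correlation). Without 2C library 1 (camera adjusted p = 0.0665) or 8C library 2 (camera adjusted p = 0.0546) or Bl library 1 (camera adjusted p = 0.0528) that list is not called. Scaling ends its call (camera adjusted p = 0.0728). BTG4 (2046 ± 237 to 126 ± 193) fell. Of 23 genome activation genes 20 rose and 2 fell, 20 and 2 over the list alone, and the list was higher (median log2 change 3.43, limma's camera adjusted p = 2.72e-09 and 0.0142 with estimated correlation). KHDC1L (2.20 ± 1.83 to 1458 ± 1072) rose.

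Translation and metabolism lists were also called between early and late embryos. In the cytosolic ribosomal protein list 55 of 71 genes rose and 1 fell, 56 and 1 over the list alone, and the list was higher (median log2 change 1.63, limma's camera adjusted p = 3.94e-14, adjusted p = 0.513 with estimated correlation). RPL6 (38.1 ± 8.25 to 951 ± 562) rose. Of 62 ribosome biogenesis genes 39 rose and 5 fell, 39 and 6 over the list alone, and the list was higher (median log2 change 1.21, limma's camera adjusted p = 8.03e-07, adjusted p = 0.222 with estimated correlation). POLR1C (0.159 ± 0.203 to 72.7 ± 24.2) rose. In the translation factor list 24 of 38 genes rose and 3 fell, 25 and 3 over the list alone, and the list was higher (median log2 change 1.23, limma's camera adjusted p = 1.40e-05, adjusted p = 0.222 with estimated correlation). EIF3I (8.53 ± 8.003 to 337 ± 157) rose. In the spliceosome list 27 of 56 genes rose and 6 fell, 29 and 6 over the list alone, and the list was higher (median log2 change 0.84, limma's camera adjusted p = 1.54e-04, adjusted p = 0.217 with estimated correlation). SRSF3 (4.11 ± 1.28 to 273 ± 118) rose. Among 56 oxidative phosphorylation genes 41 rose and 1 fell, 42 and 1 over the list alone, and the list was higher (median log2 change 1.44, limma's camera adjusted p = 5.63e-09, adjusted p = 0.551 with estimated correlation). UQCRB (0.935 ± 0.547 to 26.4 ± 27.4) rose. Of 17 glycolysis genes 12 rose and 2 fell, 12 and 2 over the list alone, and the list was higher (median log2 change 1.95, limma's camera adjusted p = 5.34e-04, adjusted p = 0.222 with estimated correlation). LDHB (2.86 ± 2.88 to 2403 ± 2109) rose.

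Lineage lists and those of other cells follow. Of 20 pluripotency and epiblast genes 13 rose and 3 fell, 14 and 3 over the list alone, and the list was higher (median log2 change 1.12, limma's camera adjusted p = 0.00356, adjusted p = 0.222 with estimated correlation). L1TD1 (0.804 ± 0.887 to 331 ± 265) rose. Of 29 trophectoderm and trophoblast genes 17 rose and 6 fell, 17 and 6 over the list alone, and the list was higher (median log2 change 0.70, limma's camera adjusted p = 0.0133, adjusted p = 0.222 with estimated correlation). Without Bl library 1 (camera adjusted p = 0.157) or Bl library 2 (camera adjusted p = 0.434) that list is not called. Scaling ends its call (camera adjusted p = 0.05). VGLL1 (listed at 0 in every early library and 14.02 ± 25.2 at late) rose. Of 3 blood and leukocyte genes 2 rose and 1 fell, 2 and 1 over the list alone.

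Camera called 48 of 220 tests of the 22 lists, and 3 of the 48 hold with an estimated correlation between members. They are genome activation from 4C to 8C and from early to late embryos, and trophectoderm from Mo to Bl. No comparison called the lists of epithelial junctions, cholesterol, primitive endoderm, stress, cumulus and granulosa cells, sperm, or blood. Of 7 cumulus and granulosa genes 0 rose and 0 fell from GV to MII, 1 and 0 over the list alone, with a median log2 change of 0.09 (limma's camera adjusted p = 0.442). Unadjusted, limma at 0.05 has 1 of them higher and 1 lower. Of 8 sperm genes 1 rose and 0 fell from MII to PN, 1 and 0 over the list alone, with a median log2 change of 0.10 (limma's camera adjusted p = 0.8). Unadjusted, it has 1 higher and 1 lower.

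**Figure D3:**
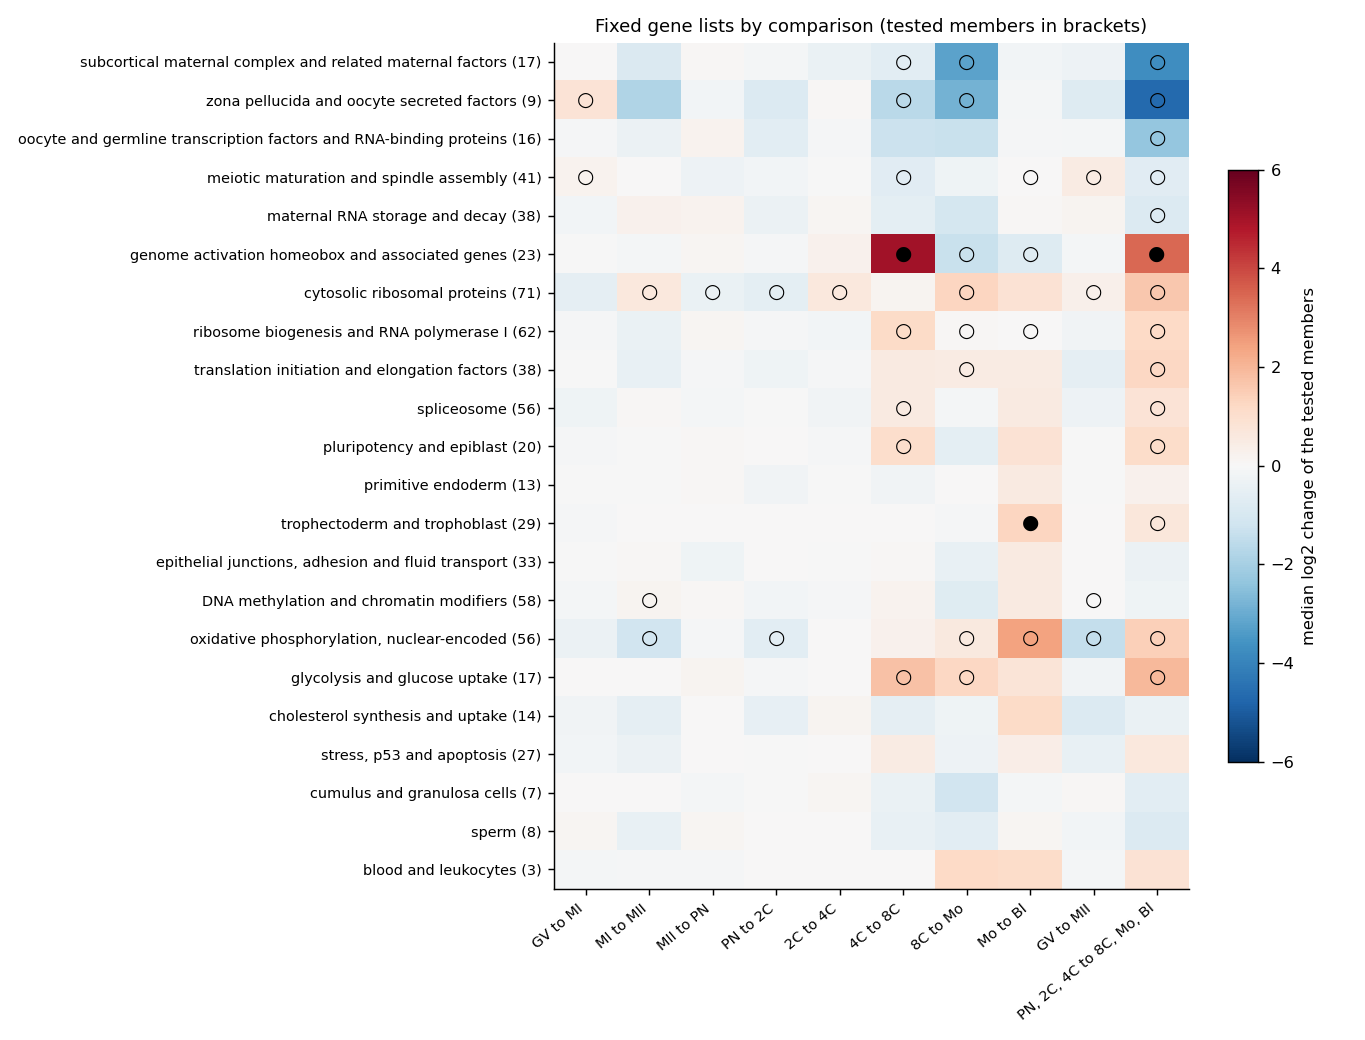
Median log2 change of each fixed gene list in each comparison. An open circle marks a camera call and a filled circle a call that also holds with an estimated correlation between members.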

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

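None of the 486 named calls and 48 list calls turned its direction under any setting; directions of other calls were not followed. Counts of called genes moved by over 1.5 times as follows; the cause was not tested. With a pseudocount of 0.1: 679 from MI to MII (1213 in the main test), 37 from PN to 2C (67), 52 from 2C to 4C (82) and 636 from GV to MII (1333). With no filter 173 from GV to MI (84), and with at least 5 RPKM in 2 libraries 53. With median-of-ratios scaling: 40 from GV to MI, 551 from MI to MII, 713 from MII to PN (1097) and 583 from GV to MII. The main test assumes stages vary alike. Fitting only those compared gives 556 from GV to MI, 3299 from MI to MII and 16 from PN to 2C. It gives 37 from 2C to 4C, 1571 from 8C to Mo (3636), 9 from Mo to Bl (2024) and 3144 from GV to MII. First detection gives 2 at Mo (6) with thresholds of 0.1 and 1 RPKM and 19 at Bl (32) with 1 and 5 RPKM. Of 48 list calls 3 remain with an estimated correlation. Leaving out 1 library (Mo library 2 for other stages was chosen after seeing the data) gives 27 to 112 from GV to MI, 234 to 1986 from MI to MII, 579 to 1662 from MII to PN, 31 to 119 from PN to 2C, 43 to 124 from 2C to 4C, 2150 to 4394 from 4C to 8C, 936 to 2328 from Mo to Bl and 231 to 2007 from GV to MII, and first detected genes of 486 to 571 at 8C, 9 to 24 at Mo and 32 to 95 at Bl. Where 1 library of a stage is left, it is assumed to vary like the others. Of the fits of the 486 named calls with 1 library left out, 392 end a call and 2899 keep it. A fit of only the stages ends 102 of the calls, the pseudocount 57, scaling 49 and no filter 29. Replicate numbers are shared by label only. The replicate block gives 53 genes from 2C to 4C and moves no other count by 1.5 times. Deviations of libraries from their stage means have a median correlation of 0.007 for the same number (78 pairs) and -0.006 for different numbers (136 pairs), and not every library correlates best with its own number.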

Other observations

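Lists that limma's camera did not call between early (PN, 2C and 4C) and late (8C, Mo and Bl) embryos also had members that limma called (mean ± SD RPKM, n = 8 and 7). The member with the smallest adjusted p is named. For primitive endoderm (3 of 13 rose and 4 fell) FRZB (61.7 ± 18.2 to 2.49 ± 4.13) fell, for DNA methylation and chromatin (19 of 58 rose and 20 fell) DNMT1 (476 ± 224 to 63.9 ± 109) fell, for stress (14 of 27 rose and 7 fell) SESN2 (0.014 ± 0.019 to 15.5 ± 11.6) rose and for epithelial junctions (12 of 33 rose and 11 fell) CTNND1 (66.8 ± 17.7 to 11.6 ± 6.07) fell. For cumulus and granulosa cells (2 of 7 rose and 4 fell) NR5A2 (0.002 ± 0.005 to 4.67 ± 3.53) rose, for sperm (2 of 8 rose and 5 fell) TNP1 (listed at 0 in every early library and 7.59 ± 16.7 at late) rose, for blood (2 of 3 rose and 1 fell) HBG2 (IMMRNTR608, 30.9 ± 29.2 to 0.743 ± 0.918) fell and for cholesterol (3 of 14 rose and 2 fell) DHCR7 (3.84 ± 1.87 to 0.574 ± 0.909) fell.

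The tests in the next paragraph were chosen after the result was seen; those on dilution, on cumulus RNA and on splits of the libraries were planned. Mo library 2 lists 8618 genes above 0, and the other libraries list 12549 to 16906. Of 10 splits of the MII and PN libraries into 3 and 3, 1 calls as many genes as the real split (1094), which is the real split itself, and the highest other calls 0; 10 splits are too few to tell. Of 100 splits of the 15 embryo libraries, 1 calls as many as the real split (6275), again itself, and the highest other calls 4448.

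In 52 entries GV and MII oocytes lie apart from MI, PN, 2C and 4C in every library (28 higher and 24 lower), and in 25 entries PN and 4C lie apart from the others (13 higher and 12 lower). Among 8 other pairs of stages not next to each other the highest count is 2. The 2 pairs were picked after their counts were seen, so this cannot rule out chance likeness of 2 stages. Of the 77, 37 have a symbol and could be searched for another entry of it: 10 (27%) have one at 1 RPKM or more. By medians over the stages 6 of those go the opposite way, but only for RPL19 and RPL15 (2) do the libraries not overlap. Reads moving between copies could explain a part; the 40 entries without a symbol could not be searched. Parents or a library batch shared by these stages could also set them apart, and 0 label fields name either, so the data cannot tell; no biological explanation was tested.

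Genes lower at 8C than at 4C could be diluted by newly abundant mRNA, since RPKM is relative. Under median-of-ratios scaling 80.7% of the 1453 lower calls stay, so a dilution that this scaling removes does not account for those. Scaling takes the middle gene as unchanged, and the table holds no spike-in, so a change in total mRNA was not measured.

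Genes higher in GV than in MII oocytes could reflect cumulus or granulosa RNA. The cumulus list's median log2 change (0.09) cannot tell, as it is NR5A2's (0.015 RPKM at GV, 0.081 at MII). Of 27 markers, TNFAIP6 and SERPINE2 exceed 5 RPKM in every GV library and neither is called lower, while 12 are at 0 at GV. Without overlap of libraries HAS2, GREM1 and EREG fell and SERPINE2, NR5A1 and NR5A2 rose. With 7 tested, such RNA is not ruled out.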
